A study of Mus musculus with 39 samples.

How the data were processed

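RNA was measured on 39 Affymetrix arrays, 1 per sample, from liver, bone marrow and spleen of B6C3F1 hybrid mice kept under reduced oxygen or control conditions for 2 hours. Per the labels' protocols, bone marrow RNA was isolated with a kit for stabilised bone marrow, liver and spleen RNA was purified on columns, and biotin-labelled targets were made from total RNA by 1 round of amplification. The deposited values are probe set intensity values on a linear scale. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set, and limma, with no version for either. The deposited intensities ran from 5.78 to 43830. Their quantiles were nearly equal within a tissue and differed between tissues, so each tissue was treated as normalized on its own.

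The intensities were converted to log2 without an offset. The value table held 45101 probe sets, of which 64 were control probe sets and were left out. The platform annotation paired 34958 probe sets with 1 gene symbol, 932 with several and 9211 with none. Probe sets with several symbols or none were not named or tested. Symbols were looked up by gene ID in a gene table of assembly GRCm38.p6, which held the gene of 34754 of these probe sets and changed 0 symbols. The array files name no genome build, so no coordinates are given. Each of the 18194 genes was represented in each tissue by its probe set of highest mean, and genes below the 30th percentile of those means were left out as dim, which left 12736 genes per tissue.

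Each tissue was fitted on its own with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the package data.table (version 1.17.8), with the contrast reduced oxygen minus control and no covariate. The Benjamini-Hochberg method adjusted p over the genes tested in that tissue, and a gene was called at adjusted p under 0.05. Every adjusted p of a gene comes from limma, and every ± beside a log2 change is its standard error. Differences between tissues in the response were interaction contrasts in 1 limma fit of all 39 arrays in 6 groups, on genes that passed the dim-gene filter in both tissues, with the probe set of highest mean over both. Overlaps of calls were compared with the count that independent lists would share (Fisher's exact test, two-sided).

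Before the data were examined, the groups, tests, alternatives, rule for named genes and 33 gene lists were fixed. The rule took, per tissue, the 12 called genes with the largest rise and the 12 with the largest fall, passing over predicted genes without a standard symbol. It also took up to 4 members of smallest p of each list described, the 6 genes of smallest p of each interaction, and the textbook hypoxia genes Vegfa, Bnip3, Egln3, Angptl4, Ddit4, Hmox1, Igfbp1 and Epo. Of those 8 genes 7 had a probe set named by 1 gene, and Epo was not analysed here. The rule did not say which lists count as described. This was narrowed after the list results were seen to lists with adjusted p under 0.05, so members of other lists are mostly given as counts.

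The lists covered responses to hypoxia, glucocorticoids and stress, metabolism, inflammation, cell cycle and survival, and markers of the cell types that the tissues could hold, all named in the report. They held 893 genes with repeats, of which 798 had a named probe set. Lists were tested in each tissue with camera of limma at a preset correlation of 0.01 between genes, with adjustment over the 33 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without comparing them with other genes, were alternatives. List members were matched through older symbols where their current symbol had no probe set. An error in that matching, which had given 4 members a probe set of another gene, was corrected after the list results had been seen, and no list moved across the threshold.

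The liver arrays of replicates 1 to 4 had a lower 30th percentile of intensity than those of replicates 5 to 8, without overlap of the ranges. The labels name no batch. A fit of the genes with the numbers 1 to 4 against 5 to 8 as a term had been fixed in advance. After the gap was seen, the term was used for lists too and the fits were repeated within each array set. Groups shared replicate numbers in the labels, so arrays with the same number in both groups of a tissue were checked for deviations from their group means that go together. In liver the same-number correlations across genes were all positive, from 0.166 to 0.535, which by the rule fixed for this check pairs the numbers. The mean was 0.303, against 0.262 for other numbers of the same array set, and 2 of 8 arrays correlated best with their own number. The pairing comes from the numbers in the labels and not from a stated shared animal or batch.

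Alternatives covered the choice of probe set, probe sets that may match several transcripts, the dim-gene filter, normalization within the tissue, centring of each array, the variance prior, array weights, 1 fit over all arrays, the replicate number as a block, an exact Wilcoxon test, the list tests and leaving out each array in turn.

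The fits were tested on simulated data with the real arrays' means and spread. At simulated log2 changes of 0.5, 1 and 2 the liver fit recovered 70.1%, 98.5% and 100% of the changed genes. The bone marrow fit recovered 64.2%, 97.0% and 100%, and the spleen fit 71.6%, 100% and 100%. Of the calls, 3.24%, 4.40% and 5.24% were unchanged genes in liver, bone marrow and spleen. The number of arrays limits the precision of all values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.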

Results

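Gene expression was measured on 39 arrays in liver, bone marrow and spleen of B6C3F1 mice, a hybrid of the C57BL/6 and C3H strains, after 2 hours of reduced oxygen or of control conditions. Liver and spleen each had 8 control and 8 reduced oxygen samples, and bone marrow had 3 control and 4 reduced oxygen samples. The sample titles call the control arms vehicle, naming no substance, and do not say whether the reduced oxygen mice received it. The labels do not say whether samples of a group, or tissues of the same number, came from separate or the same mice. The p-values then measure only the spread between samples, which may be technical. The design asks which transcripts responded in each tissue, and whether the response differed between tissues. No array of a tissue duplicated another. The median log2 intensity of an array was 5.21 to 5.33 in liver, 6.22 to 6.29 in bone marrow and 6.16 to 6.20 in spleen.

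Cell type markers in the control arrays followed the tissue labels. Hepatocyte markers had a median log2 intensity of 14.4 in liver, 4.68 in bone marrow and 4.76 in spleen. Erythroid markers stood at 11.9 in bone marrow, 10.3 in spleen and 5.53 in liver, and varied widely between control spleens, with an SD of 1.17 (n = 8). The tissues appear to have been normalized separately, so these levels are descriptions only.

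In liver, reduced oxygen raised transcripts of hypoxia, glucocorticoid and immediate early responses. Ddit4, an inhibitor of mTORC1 induced by hypoxia and glucocorticoids, rose 28.7-fold, from a log2 intensity of 6.67 ± 0.44 (SD, n = 8) in control to 11.51 ± 0.50 (SD, n = 8). Igfbp1, a liver-secreted binding protein of insulin-like growth factors and a textbook hypoxia target, rose 7.62-fold, from 11.14 ± 0.54 to 14.07 ± 0.13 (SD, n = 8 each). Arrdc3, an arrestin-domain protein, had the largest fall, from 10.77 ± 0.40 to 7.89 ± 0.63 (SD, n = 8 each).

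Of 12736 genes tested in liver, 1413 were called, 494 higher and 919 lower. At least 1.5-fold change was reached by 241 higher and 230 lower genes. With the array set, replicates 1 to 4 or 5 to 8, as a term 2666 genes were called, 811 higher and 1855 lower, including all 1413. Within replicates 1 to 4 there were 780 calls, 306 higher and 474 lower, and within 5 to 8 there were 1894, 590 higher and 1304 lower. All 64 called genes named for liver kept their call with the set term and their direction in both sets by the same probe set. Fitted alone, replicates 1 to 4 ended 20 of these calls (adjusted p to 0.578) and 5 to 8 ended those of Sqle (adjusted p = 0.0581) and Plek, at 0.03 (adjusted p = 0.899), where another probe set of Plek was the brightest. For 7 of the 64 a set differed over 1.5 times from the whole, with 1.53 within replicates 1 to 4 and 5.43 within 5 to 8 for Lcn2, 0.97 and 2.62 for Prtn3, 1.01 and 0.48 for Atf3, 0.35 and 0.997 for Saa4, 0.29 and 0.94 for Plek, 0.16 and 0.62 for Clec1b and -1.998 and -0.97 for Fzd7. With the replicate number as a block, 2385 liver genes changed. The median change of all genes was -0.03, and scaling moved it by less than 0.1.

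The largest rises in liver after Ddit4 (4.84 ± 0.21, adjusted p = 7.78e-12) included both metallothioneins, metal-binding proteins that respond to zinc and glucocorticoids. Mt2 rose by 4.40 ± 0.50 (adjusted p = 6.36e-06) and Mt1 by 3.45 ± 0.41 (adjusted p = 9.06e-06). Snhg3, a host gene of small nucleolar RNAs, rose by 3.66 ± 0.12. Stress and growth-arrest genes followed, with Gadd45g at 3.52 ± 0.24 and Cdkn1a, the cyclin-dependent kinase inhibitor p21, at 2.92 ± 0.31. Noct rose by 3.24 ± 0.27. Pfkfb3, whose product makes the glycolysis activator fructose 2,6-bisphosphate, rose by 3.00 ± 0.25. The AP-1 subunit Jun rose by 3.07 ± 0.24 and the MAP kinase phosphatase Dusp1 by 3.01 ± 0.14. The adjusted p of the genes after Mt1 ran up to 1.85e-06 for Cdkn1a. Lcn2, an iron-siderophore-binding protein of neutrophils and of the hepatic acute phase, rose by 3.48 ± 1.05 (adjusted p = 0.0366). It was the only one of these 12 whose groups overlapped, with 7.40 ± 1.34 in control and 10.88 ± 3.20 under reduced oxygen (SD, n = 8 each). Its adjusted p ran from 0.0116 to 0.0796 with 1 array left out, and the call ended for 11 of 16 arrays, all but controls 3 and 4 and reduced oxygen 1, 2 and 5. It also ended with a robust variance prior with trend (adjusted p = 0.0840), as did those of Cd14 and Prtn3. The exact Wilcoxon test ended the calls of Cd14, Clec1b, Insig2, Lcn2, Pfkl, Prtn3 and Slc30a10 (adjusted p to 0.185), quantile normalization or no dim-gene filter those of Insig2 and Slc30a10, the mean of probe sets that of Slc30a10 (adjusted p = 0.0776) and centring that of Mx2 (adjusted p = 0.0585).

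Among the largest falls in liver after Arrdc3 (-2.88 ± 0.23, adjusted p = 5.66e-08) were Phlda1 at -2.22 ± 0.25 and Osgin1, an oxidative stress-induced growth inhibitor, at -2.11 ± 0.20. Mup10 fell by 2.10 ± 0.19, but major urinary proteins form a family of near-identical copies, so its identity is uncertain. The transcription factor genes Foxa1, Hhex and Foxq1 were at -1.93 ± 0.13, -1.74 ± 0.26 and -1.68 ± 0.27. Id3, an inhibitor of basic helix-loop-helix factors, fell by 1.63 ± 0.16 and the zinc finger gene Zfp866 by 1.71 ± 0.13. Clec2d, a C-type lectin ligand of an NK cell receptor, fell by 1.60 ± 0.22. The succinate receptor Sucnr1 fell by 1.55 ± 0.36 (adjusted p = 0.00816), the weakest of these 12, and the Wnt receptor Fzd7 by 1.49 ± 0.21. The groups overlapped for Sucnr1, Foxq1 and Hhex.

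Of the hypoxia genes fixed in advance, Vegfa, the endothelial growth factor, rose by 0.66 ± 0.12 in liver (adjusted p = 0.000813) and Bnip3, a mitophagy receptor, by 0.70 ± 0.13 (adjusted p = 0.000863). Hmox1, heme oxygenase, rose by 1.08 ± 0.27 (adjusted p = 0.0126). Egln3, a prolyl hydroxylase that marks HIF for degradation, was 0.11 ± 0.14 (adjusted p = 0.701). Angptl4, a lipoprotein lipase inhibitor, was 0.05 ± 0.12 by its brightest probe set (adjusted p = 0.871), while its other probe set gave 3.28. The liver Angptl4 log2 fold change over the mean of both was 1.67 (adjusted p = 6.18e-06).

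**Figure D1:**
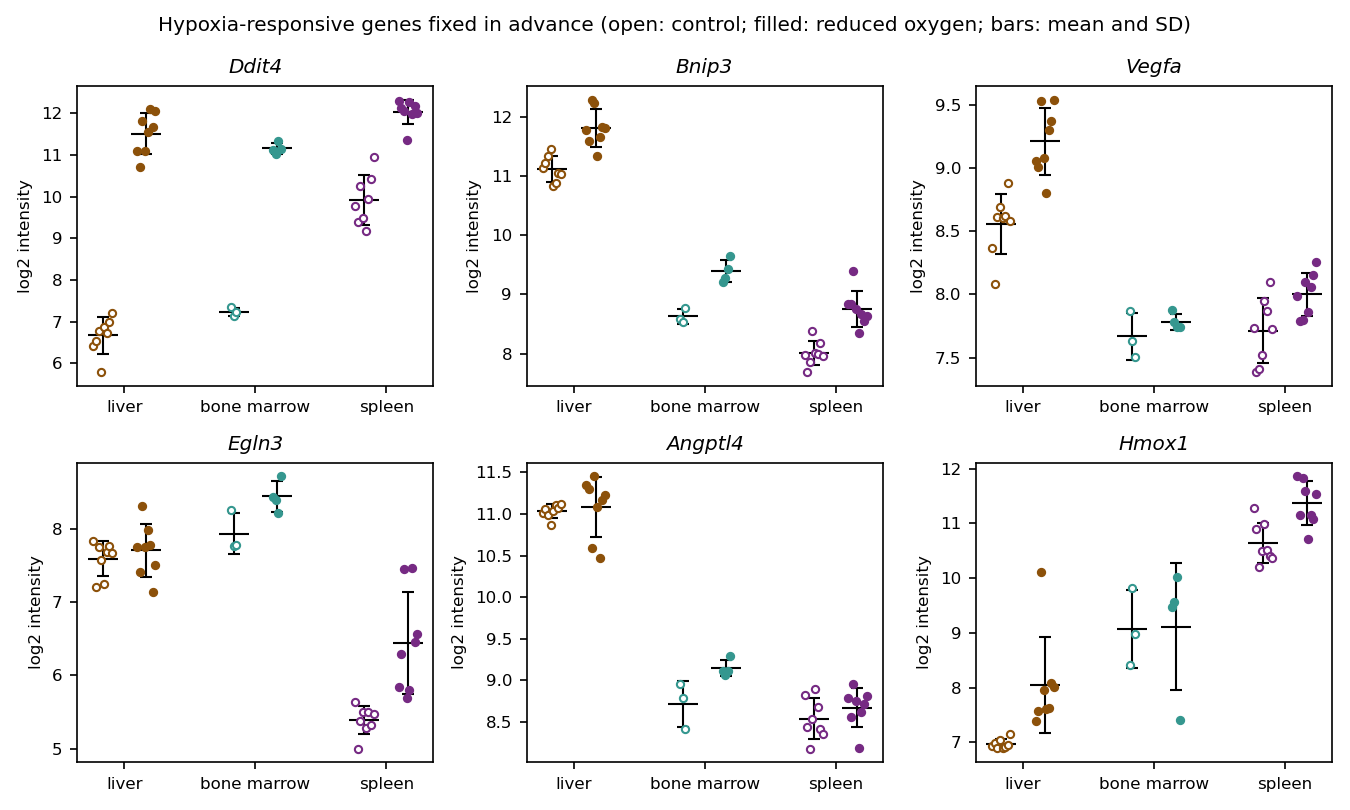
Log2 intensity of Ddit4, Bnip3, Vegfa, Egln3, Angptl4 and Hmox1 on each array of liver, bone marrow and spleen, with open points for control, filled points for reduced oxygen, and bars for the mean and SD. The groups lie apart for Ddit4 in all 3 tissues, while Angptl4 by this probe set overlaps between the liver groups.

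Of the 33 lists, 15 passed in liver at the preset correlation, and 5 of them also with an estimated correlation: glucocorticoid-responsive genes, hypoxia-inducible targets, immediate early genes, the stress response list and p53 targets. Other splits of the liver arrays gave up to 18 lists at the preset correlation, so chance was not excluded for that number. With the array set as a term, the same 15 passed. Glucocorticoid-responsive genes had 15 of 27 members higher and 1 lower (18 and 1 adjusted over the list alone), with median 0.56 (adjusted p = 2.19e-21, and 1.41e-05 with an estimated correlation). Examples were Ddit4, Dusp1, Gadd45g and the kinase Sgk1 at 2.23 ± 0.12. The hypoxia list had 15 of 33 higher and 1 lower (17 and 1 adjusted over the list alone), with median 0.29 (adjusted p = 1.17e-17, and 0.00442 with an estimated correlation). Besides Ddit4, Igfbp1 and Pfkfb3, the vasodilator peptide gene Adm rose by 1.22 ± 0.12. Immediate early genes had 14 of 26 higher and 1 lower (14 and 2 adjusted over the list alone), with median 0.43 (adjusted p = 2.45e-14, and 0.00575 with an estimated correlation). Fos rose by 2.03 ± 0.17 and Gadd45b by 1.82 ± 0.15, beside Jun and Dusp1.

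The list of the unfolded protein and integrated stress response had 5 of 26 higher and 1 lower in liver (9 and 1 adjusted over the list alone), with median 0.22 (adjusted p = 2.04e-06, and 0.0356 with an estimated correlation). Chac1, a glutathione-degrading enzyme, rose by 1.29 ± 0.20, Ppp1r15a, which restores translation, by 0.75 ± 0.09 and Atf3 by 0.75 ± 0.12, while Atf5 fell by 0.39. The p53 list had 5 of 19 higher and 2 lower (5 and 2 adjusted over the list alone), with median 0.06 (adjusted p = 0.00235, and 0.0356 with an estimated correlation). Its leading members were Cdkn1a, the antiproliferative factor Btg2 at 2.90 ± 0.24, Trp53inp1 at 2.42 ± 0.13 and the kinase Plk3 at 2.02 ± 0.22. The p53 median was -0.02 within replicates 5 to 8, and the liver list: p53 targets had medians of 0.02 to 0.03 without controls 3, 4 or 7 or reduced oxygen 3, 5, 7 or 8 (adjusted p to 0.00367).

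Lists of metabolic genes passed in liver only at the preset correlation. Gluconeogenesis and amino acid catabolism had 8 of 22 higher and 1 lower (10 and 3 adjusted over the list alone), with median 0.21 (adjusted p = 1.02e-06, but 0.139 with an estimated correlation). G6pc, the catalytic unit of glucose-6-phosphatase, rose by 1.21 ± 0.13, the tyrosine-degrading enzyme Tat by 1.05 ± 0.13, the urea cycle enzyme Ass1 by 1.80 ± 0.20 and the amino acid transporter Slc38a2 by 1.84 ± 0.12. The median was 0.31 and 0.11 within the sets and 0.14 without reduced oxygen 3. Glycolysis enzymes had 5 of 17 higher and 0 lower (7 and 1 adjusted over the list alone), with median 0.16 (adjusted p = 0.00263, but 0.0841 with an estimated correlation). Aldoa rose by 0.55, Pkm by 0.53, Ldha by 0.45 and Pfkl by 0.41. The median was 0.07 and 0.15 within the sets. Pfkl lost its call without controls 4 or 8 or reduced oxygen 3, 7 or 8 (adjusted p to 0.0595). Cholesterol and fatty acid synthesis had 3 of 26 higher and 0 lower (5 and 0 adjusted over the list alone), with median 0.13 (adjusted p = 0.000168, but 0.268 with an estimated correlation). Thrsp, a lipogenesis factor, rose by 1.54 ± 0.22, Sqle by 0.62 and Insig2 by 0.41, while Elovl6 was 0.42 (adjusted p = 0.0567, and adjusted p = 0.0267 with the block). The median was 0.22 and 0.01 within the sets and 0.09 without control 3. Metallothioneins and zinc handling had 4 of 10 higher and 0 lower (4 and 1 adjusted over the list alone), with median 0.08 (adjusted p = 0.000898, but 0.0566 with an estimated correlation). The zinc transporters Slc39a14 and Slc30a10 rose by 1.18 ± 0.17 and 0.50. The liver list: metallothioneins and zinc handling had medians of 0.14 and 0.12 without reduced oxygen 2 and 5, and 0.25 and 0.24 within the array sets. Insig2 and Slc30a10 lost their calls for 11 and 10 of 16 arrays left out (adjusted p to 0.0941 and 0.0932). Oxidative phosphorylation had 0 of 33 members called by limma over all genes or adjusted over the list alone, with median -0.12 (adjusted p = 0.00172, but 0.437 with an estimated correlation). Without adjustment 0 members were higher and 9 lower at p under 0.05, and the exact Wilcoxon test called 5. The leading members were Ndufv1 at -0.25, Atp5d at -0.20, Cox5b at -0.17 and Cyc1 at -0.15. The median was -0.03 and -0.18 within the sets. Elovl6 passed without control 1 or reduced oxygen 5 or 7, Ndufv1 without reduced oxygen 1, 2 or 4 and Atp5d and Cox5b without reduced oxygen 2 (adjusted p from 0.0189). With the block Ndufv1, Atp5d and Cox5b passed (adjusted p = 0.0296, 0.0471 and 0.0461).

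Inflammatory and blood cell lists passed in liver only at the preset correlation. Acute phase and inflammation had 7 of 30 higher and 0 lower (13 and 0 adjusted over the list alone), with median 0.32 (adjusted p = 5.04e-09, but 0.268 with an estimated correlation). The NF-kappaB regulators Nfkbiz, Tnfaip3 and Nfkbia rose by 1.41 ± 0.37, 1.00 ± 0.23 and 0.56, and the serum amyloid gene Saa4 by 0.67. The median was 0.09 and 0.46 within the sets. Neutrophil markers had 4 of 15 higher and 0 lower (4 and 0 adjusted over the list alone), with median 0.07 (adjusted p = 0.0221, but 0.505 with an estimated correlation). These were Lcn2, S100a8 at 1.81 ± 0.48, S100a9 at 1.39 ± 0.36 and Prtn3 at 1.80 ± 0.55 (adjusted p = 0.0391, to 0.0858 with 1 array left out, where 11 of 16 ended the call). S100a8 stood at 4.59, 4.79 and 4.81 in reduced oxygen 1, 2 and 5, within the control range of 4.09 to 4.82, and at 5.69 to 8.49 in the others. Its controls lay below every liver array median, so its log2 change may be understated. The list median was -0.0047 and 0.16 within the sets. The list's call ended without controls 1 or 4 or reduced oxygen 6, 7 or 8 (adjusted p to 0.0761), and its median was 0.04 without control 1 or reduced oxygen 5 and 0.14 without reduced oxygen 4. Macrophage markers had 1 of 26 higher and 0 lower (0 and 0 adjusted over the list alone), with median 0.17 (adjusted p = 0.00384, but 0.57 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 rose by 1.42 ± 0.40 (adjusted p = 0.0274, to 0.0537 without reduced oxygen 6, 7 or 8), while Cd163 was 0.44, Marco 0.41 and Vcam1 0.23. Vcam1 had another probe set at 1.97, and Marco and Vcam1 passed with the block (adjusted p = 0.0382 and 0.0144). The macrophage median was -0.19 and 0.49 within the sets. The liver list: macrophages and monocytes had a median of 0.10 without control 4 and of 0.08 without reduced oxygen 6, which ended the call (adjusted p = 0.0543). Megakaryocyte markers had 2 of 13 higher and 0 lower (2 and 0 adjusted over the list alone), with median 0.04 (adjusted p = 0.0278, but 0.296 with an estimated correlation). Plek rose by 0.61 and Clec1b by 0.39, while Itgb3 was 0.31 and Pf4 0.28. The list's call ended without controls 1, 3 or 4 or reduced oxygen 5, 6, 7 or 8 (adjusted p to 0.0710), and its median was 0.06 to 0.08 without controls 3 or 6 or reduced oxygen 2, 3 or 4. Interferon-stimulated genes had 2 of 26 higher and 1 lower (3 and 1 adjusted over the list alone), with median 0.10 (adjusted p = 0.0278, but 0.545 with an estimated correlation). Usp18 rose by 0.97 ± 0.12 and Mx2 by 0.33, the transcription factor Irf1 fell by 1.23 ± 0.09, and Xaf1 was 0.39. The median was -0.03 and 0.21 within the sets. The list's call ended without controls 3, 6 or 7 or reduced oxygen 6 or 7 (adjusted p to 0.0903), and its median was 0.05 to 0.06 without controls 6 or 7 or reduced oxygen 6. Mx2 and Clec1b lost their calls for 11 and 7 of 16 arrays left out (adjusted p to 0.0823 and 0.0636). Xaf1 passed without control 1 or reduced oxygen 1, 2 or 5, Marco without reduced oxygen 1 and Cd163 without reduced oxygen 5 (adjusted p from 0.0215).

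The other 18 lists did not pass in liver. Cell cycle genes had 2 higher and 1 lower of 22 (adjusted p = 0.0529), adipocyte markers 2 and 1 of 9 (adjusted p = 0.0774), apoptosis genes 4 and 3 of 23 (adjusted p = 0.0912) and the circadian clock 4 and 2 of 18 (adjusted p = 0.0923). PPAR-alpha targets had 1 and 3 of 23 and iron handling 3 and 1 of 21 (adjusted p = 0.168 each). Hepatocyte markers had 1 and 0 of 19 (adjusted p = 0.295), heat shock proteins 2 and 2 of 19 (adjusted p = 0.378), erythroid markers 1 and 3 of 18 (adjusted p = 0.504), and angiogenesis 4 and 2 of 32, NRF2 targets 1 and 2 of 19 and bile acid and drug metabolism 0 and 1 of 20 (adjusted p = 0.641 each). Pancreatic acinar markers had 1 and 1 of 10 (adjusted p = 0.621). No member was called by limma, over all genes or adjusted over the list alone, among B cell markers (0 of 14, adjusted p = 0.494), ribosomal proteins (0 of 22, adjusted p = 0.549), bone and stromal markers (0 of 17, adjusted p = 0.685), skeletal muscle (0 of 10, adjusted p = 0.71) and T and NK cell markers (0 of 12, adjusted p = 0.799). Of these, 1 B cell marker was higher and 1 stromal marker lower at an unadjusted p under 0.05, and the exact Wilcoxon test called 0. Adjusted over the list alone, the counts that differed were 5 and 3 for apoptosis, 1 and 5 for PPAR-alpha targets, 3 and 4 for iron handling, 1 and 7 for erythroid markers, 0 and 0 for bile acid and drug metabolism and 4 and 3 for angiogenesis. Median, mean and test differed in sign for iron handling, hepatocytes, angiogenesis and erythroid markers.

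In bone marrow, glucocorticoid-responsive genes made up the clearest group. Ddit4 rose 15.2-fold, from a log2 intensity of 7.23 ± 0.11 (SD, n = 3) to 11.16 ± 0.13 (SD, n = 4). Per1, a clock gene that glucocorticoids induce, rose by 2.72 ± 0.14, and Ccn1, a matrix-associated immediate early protein, from 6.90 ± 0.53 (SD, n = 3) to 10.11 ± 0.25 (SD, n = 4). The largest fall was that of Snai2, a zinc finger repressor, from 8.39 ± 0.21 (SD, n = 3) to 6.86 ± 0.05 (SD, n = 4).

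Of 12736 genes tested in bone marrow, 979 were called, 352 higher and 627 lower. At least 1.5-fold change was reached by 114 higher and 108 lower. Without control 2, 447 bone marrow genes changed, and the count was 650 without control 3, 408 without reduced oxygen 2 and 469 without reduced oxygen 3. In 1 fit over all arrays it was 310, and the calls of Bhlhe40, Chac2, Col3a1, Egr1, Il2rb, Lin28a, Lum, Mt1, Mt2 and Ncr1 ended (adjusted p from 0.0613 to 0.789).

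Ddit4 rose by 3.93 ± 0.09 (adjusted p = 2.04e-07) and Ccn1 by 3.21 ± 0.23 (adjusted p = 0.000267). Dusp1 rose by 2.39 ± 0.10, Errfi1, a feedback inhibitor of the EGF receptor, by 2.05 ± 0.14 and Mt2 by 2.01 ± 0.14. Cirbp, a cold-inducible RNA-binding protein, rose by 1.86 ± 0.12, the glucocorticoid-induced factor Klf9 by 1.82 ± 0.08 and Pik3ip1, an inhibitor of PI3 kinase, by 1.79 ± 0.10. Other probe sets of Klf9 ranged from 0.03. The replacement histone gene H3f3b rose by 1.76 ± 0.14 and Fos by 1.65 ± 0.11. Zbtb16, a transcriptional repressor of blood cells that glucocorticoids induce, rose by 1.67 ± 0.30 (adjusted p = 0.0145). Its call was lost without control 2 (adjusted p = 0.0600) and without control 3 (adjusted p = 0.0536). The other 11 largest rises had adjusted p of at most 0.000393 for H3f3b.

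After Snai2 (-1.52 ± 0.09, adjusted p = 0.000206), Olr1, a receptor of oxidised low-density lipoprotein, fell by 1.16 ± 0.18 and the endothelial factor Sox18 by 1.13 ± 0.08. Ubxn7 was at -1.10 ± 0.09, Thap2 at -1.07 ± 0.11, the glutathione-degrading enzyme Chac2 at -1.002 ± 0.12 and Ifit1bl2 at -0.98 ± 0.13. Ern1, the endoplasmic reticulum stress sensor IRE1, fell by 0.98 ± 0.11, Snord89 by 0.97 ± 0.08, Zfp397 by 0.93 ± 0.06 and Cebpg, a partner of other C/EBP factors, by 0.91 ± 0.07. Lin28a, a regulator of let-7 RNAs, fell by 0.92 ± 0.17 (adjusted p = 0.0177, and 0.0551 without reduced oxygen 2). Other probe sets of Cebpg, Ern1 and Ubxn7 gave 0.61, 0.17 and 0.00, and 1 of 3 probe sets of Zfp397 had its sign.

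Of the hypoxia genes fixed in advance, Bnip3 rose by 0.77 ± 0.11 in bone marrow (adjusted p = 0.0068). Egln3 was 0.51 ± 0.15 (adjusted p = 0.0731), but passed at 0.67 without control 1 (adjusted p = 0.0293). Vegfa was 0.12 ± 0.09 (adjusted p = 0.465), and 0.03 to 0.22 with 1 array left out. Hmox1 was 0.05 ± 0.59 (adjusted p = 0.972). Angptl4 was 0.43 ± 0.12 (adjusted p = 0.07, and 0.0375 without control 1) by its brightest probe set and 0.78 by the other, and the bone marrow Angptl4 log2 fold change over their mean was 0.60 (adjusted p = 0.0221). Igfbp1 was tested only in liver.

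Of the 33 lists 8 passed in bone marrow at the preset correlation, and of these glucocorticoid-responsive genes also with an estimated correlation. Other splits of the 7 arrays gave up to 12 lists, so chance was not excluded for that number. Glucocorticoid-responsive genes had 18 of 26 higher and 0 lower (23 and 0 adjusted over the list alone), with median 0.88 (adjusted p = 1.06e-26, and 0.0108 with an estimated correlation). Ddit4, Dusp1, Klf9 and Per1 led. The hypoxia list had 7 of 34 higher and 0 lower (10 and 1 adjusted over the list alone), with median 0.13 (adjusted p = 0.000166, but 0.273 with an estimated correlation). Ankrd37 rose by 1.55 ± 0.16, Adm by 0.91 ± 0.07 and Bhlhe40 by 0.70 ± 0.06. Immediate early genes had 7 of 27 higher and 2 lower (10 and 3 adjusted over the list alone), with median 0.07 (adjusted p = 0.0105, but 0.290 with an estimated correlation). Egr1 rose by 1.53 ± 0.16, beside Dusp1, Fos and Ccn1. This bone marrow list: immediate early genes had medians of 0.11 without control 1, 0.03 without control 2 and 0.12 without reduced oxygen 2. The circadian clock had 2 of 17 higher and 0 lower (5 and 1 adjusted over the list alone), with median 0.10 (adjusted p = 0.018, but 0.290 with an estimated correlation). Per1 and Bhlhe40, also on lists above, rose, while Nr1d2 was 0.63 and Clock 0.26 (adjusted p = 0.0422 without reduced oxygen 4). The bone marrow list: circadian clock had medians of 0.05 without control 1, 0.15 without reduced oxygen 3 and 0.06 without reduced oxygen 4, and did not pass over the mean of all probe sets (adjusted p = 0.0548). Metallothioneins and zinc handling had 2 of 10 higher and 0 lower (4 and 1 adjusted over the list alone), with median 0.17 (adjusted p = 0.0105, but 0.273 with an estimated correlation). Mt2 rose and Mt1 rose by 1.15 ± 0.18, while Slc30a10 was 0.41 and the metal-responsive factor Mtf1 -0.38. Mtf1 was 0.23 without control 1 and 0.08 without control 3.

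Lists of bone and stromal, skeletal muscle and T and NK cell markers passed in bone marrow only at the preset correlation. Bone and stromal markers had 6 of 19 higher and 1 lower (9 and 1 adjusted over the list alone), with median 0.31 (adjusted p = 0.000166, but 0.290 with an estimated correlation). Lum rose by 0.66, bone sialoprotein Ibsp by 0.57 and Col3a1 by 0.57, and the collagenase Mmp13 fell by 0.72. Lum lost its call without control 1 or 2 or reduced oxygen 2 or 3 (adjusted p to 0.0702), Mmp13 without any array but control 1 and reduced oxygen 1 (adjusted p to 0.0819), and Ibsp without reduced oxygen 3 (adjusted p = 0.0507). Skeletal muscle had 0 of 17 members called by limma over all genes or adjusted over the list alone, with median 0.52 (adjusted p = 0.000166, but 0.714 with an estimated correlation). Without adjustment 7 members were higher and 0 lower at p under 0.05. The exact Wilcoxon test called 0, but with 3 against 4 arrays it cannot call any gene. Tnnt3 was 0.88, Ckm 0.55, Tnni2 0.52 and Eno3 0.28. Without control 3 the first 3 were 0.46, 0.33 and 0.28, and all 4 passed with array weights. The bone marrow list: skeletal muscle had a median of 0.24 without control 3. T and NK cell markers had 2 of 23 higher and 1 lower (4 and 1 adjusted over the list alone), with median 0.14 (adjusted p = 0.0105, but 0.376 with an estimated correlation). The cytokine receptor genes Il7r and Il2rb rose by 0.85 ± 0.17 and 0.29, the NK receptor Ncr1 fell by 0.25, and perforin Prf1 was 0.28. Il2rb and Ncr1 lost their calls without any 1 of the 7 arrays (adjusted p to 0.111 and 0.107), and Il7r without reduced oxygen 2 (adjusted p = 0.0534). The bone marrow list: T and NK cells had a median of 0.07 without control 1.

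The other 25 lists did not pass in bone marrow. Apoptosis genes had 7 higher and 1 lower of 24 and gluconeogenesis 1 and 1 of 13 (adjusted p = 0.077 each). Interferon-stimulated genes had 0 and 1 of 28 and erythroid markers 0 and 1 of 30 (adjusted p = 0.148 each). Heat shock proteins had 1 and 0 of 18 and angiogenesis 0 and 2 of 33 (adjusted p = 0.184 each), and cell cycle genes 0 and 6 of 33 and adipocyte markers 2 and 0 of 8 (adjusted p = 0.21 each). Macrophage markers had 1 and 2 of 26 (adjusted p = 0.213), p53 targets 3 and 1 of 19 (adjusted p = 0.236), iron handling 1 and 1 of 18 (adjusted p = 0.455) and ribosomal proteins 0 and 1 of 22 (adjusted p = 0.509). Acute phase genes had 2 and 2 of 18 (adjusted p = 0.622), the stress response list 2 and 0 of 28 (adjusted p = 0.671) and PPAR-alpha targets 1 and 0 of 18 (adjusted p = 0.685). Cholesterol and fatty acid synthesis had 2 and 1 of 26 and NRF2 targets 0 and 1 of 20 (adjusted p = 0.872 each). No member was called by limma, over all genes or adjusted over the list alone, among neutrophil markers (0 of 23, adjusted p = 0.0835), pancreatic acinar markers (0 of 8, adjusted p = 0.21), bile acid and drug metabolism (0 of 8, adjusted p = 0.456), B cell markers (0 of 26, adjusted p = 0.464), hepatocytes (0 of 4, adjusted p = 0.509), oxidative phosphorylation (0 of 33, adjusted p = 0.509), glycolysis enzymes (0 of 16, adjusted p = 0.845) and megakaryocytes (0 of 18, adjusted p = 0.859). At an unadjusted p under 0.05 there were 4 neutrophil markers lower, 2 acinar markers higher, 3 B cell markers higher and 3 lower, and 3 glycolysis enzymes higher and 1 lower. The exact Wilcoxon test called 0, as it must with 3 against 4 arrays. Adjusted over the list alone, the counts that differed were 8 and 3 for apoptosis, 2 and 1 for gluconeogenesis, 2 and 2 for heat shock, 0 and 7 for cell cycle, 3 and 0 for adipocytes, 6 and 1 for p53, 3 and 3 for acute phase and for PPAR-alpha targets, and 0 and 0 for erythroid markers and ribosomal proteins. Median, mean and test differed in sign for glycolysis, megakaryocytes, cholesterol synthesis and NRF2 targets.

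In spleen, glucocorticoid-responsive genes stood out, with 22 of 28 members higher. Errfi1 had the largest rise, from a log2 intensity of 8.36 ± 0.43 to 11.01 ± 0.31 (SD, n = 8 each). Il1r2, a decoy receptor of interleukin-1 that glucocorticoids induce, rose from 6.56 ± 0.29 to 8.98 ± 1.26, and Ddit4 rose 4.31-fold, from 9.92 ± 0.60 to 12.03 ± 0.29 (SD, n = 8 each). Pcdh18, a protocadherin, had the largest fall, from 7.17 ± 0.34 to 5.37 ± 0.26 (SD, n = 8 each).

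Of 12736 genes tested in spleen, 2470 were called, 871 higher and 1599 lower. At least 1.5-fold change was reached by 181 higher and 247 lower. With the array set as a term 2812 were called, 1067 higher and 1745 lower. Within replicates 1 to 4, 482 spleen genes changed, 245 higher and 237 lower, and within 5 to 8 there were 3293, 1167 higher and 2126 lower. All 51 called genes named for spleen kept their call with the set term and their direction in both sets. Fitted alone, replicates 1 to 4 ended 27 of these calls and 5 to 8 ended 6 (adjusted p to 0.428 and 0.423). For 3 of the 51 a set differed as much, with 0.61 and 0.25 for Nrgn, 0.67 and 0.17 for C1qc and 0.14 and 0.31 for Txnrd1. Without control 5 and reduced oxygen 2, the arrays with the most pancreatic acinar transcripts of their groups, 2352 genes were called, without Cxcr5 and Txnrd1 (adjusted p to 0.0548). The exact Wilcoxon test ended the calls of C1qc, Itgam, Mmp9 and Nrgn (adjusted p to 0.0874), 1 fit over all arrays those of C1qc and Hmox1 (adjusted p to 0.0695), the mean of probe sets those of Fcer2a and Pax5 (adjusted p to 0.106) and the erythroid list mean as a covariate those of Fcer2a and Txnrd1 (adjusted p to 0.0656).

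Errfi1 rose by 2.65 ± 0.17 (adjusted p = 3.44e-08) and Il1r2 by 2.42 ± 0.41 (adjusted p = 0.000465). Dusp1 rose by 2.36 ± 0.12, Pdk4, a kinase that restrains glucose oxidation, by 2.17 ± 0.18 and Fos by 2.16 ± 0.23. Mmp8, the neutrophil collagenase, rose by 2.15 ± 0.49 (adjusted p = 0.00496), and its groups overlapped. Ddit4 was at 2.11 ± 0.21, Neto2 at 2.09 ± 0.22 and H3f3b at 1.98 ± 0.20. Kcne4, a potassium channel subunit, rose by 1.97 ± 0.08 (adjusted p = 1.47e-10). Dnah2 rose by 1.86 ± 0.18 by its brightest probe set, with another at 0.01, and Apold1, an endothelial early response gene, by 1.79 ± 0.27. Among the largest falls after Pcdh18 (-1.81 ± 0.14, adjusted p = 2.58e-07) were Egr3 at -1.69 ± 0.24, with another probe set at 0.06, and Rbm12b1 at -1.45 ± 0.17. Thap2 fell by 1.43 ± 0.13, Zfp467 by 1.33 ± 0.12, Id3 by 1.16 ± 0.13 and the TNF receptor adaptor Traf1 by 1.14 ± 0.16. Zfp429 fell by 1.10 ± 0.10, Cebpg by 1.08 ± 0.09, with another probe set at 0.31, and Tbx21, the T-bet factor, by 1.06 ± 0.14. Ttpal fell by 1.04 ± 0.09 and Zfp397 by 1.03 ± 0.09.

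Of the hypoxia genes fixed in advance, Egln3 rose by 1.06 ± 0.23 in spleen (adjusted p = 0.00394), Bnip3 by 0.75 ± 0.12 (adjusted p = 0.000317) and Hmox1 by 0.72 ± 0.18 (adjusted p = 0.00767). Vegfa was 0.29 ± 0.10 (adjusted p = 0.0617), and passed without reduced oxygen 2 or controls 5 or 7 (adjusted p from 0.0230). Angptl4 was 0.13 ± 0.11 (adjusted p = 0.444) by its brightest probe set and 0.85 by the other, and the spleen Angptl4 log2 fold change over their mean was 0.49 (adjusted p = 0.00123).

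Of the 33 lists 11 passed in spleen at the preset correlation, and of these glucocorticoid-responsive genes also with an estimated correlation. Other splits of the arrays gave up to 17 lists, so chance was not excluded for that number. Glucocorticoid-responsive genes had 22 of 28 higher and 0 lower (23 and 0 adjusted over the list alone), with median 1.27 (adjusted p = 5.08e-24, and 0.00247 with an estimated correlation). Per1 rose by 1.62, beside Dusp1, Errfi1 and Pdk4. The hypoxia list had 11 of 34 higher and 0 lower (15 and 0 adjusted over the list alone), with median 0.21 (adjusted p = 5.04e-08, but 0.104 with an estimated correlation). Ankrd37 rose by 1.57, Adm by 1.14 and Bhlhe40 by 0.68, beside Ddit4. The median was 0.25 and 0.13 within the sets. Glycolysis enzymes had 6 of 17 higher and 0 lower (6 and 0 adjusted over the list alone), with median 0.25 (adjusted p = 0.000676, but 0.609 with an estimated correlation). Tpi1 rose by 0.46, Pfkl by 0.41, Ldha by 0.29 and Gapdh by 0.24. NRF2 targets had 4 of 21 higher and 0 lower (4 and 0 adjusted over the list alone), with median 0.17 (adjusted p = 0.00711, but 0.765 with an estimated correlation). Beside Hmox1, glutathione reductase Gsr rose by 0.56, Abcc4 by 0.46 and thioredoxin reductase Txnrd1 by 0.23. The median was 0.09 and 0.20 within the sets. Txnrd1 lost its call for 9 of 16 arrays left out (adjusted p to 0.0777). Oxidative phosphorylation had 0 of 33 members called by limma over all genes or adjusted over the list alone, with median 0.09 (adjusted p = 0.00548, but 0.765 with an estimated correlation). Without adjustment 6 members were higher and 0 lower at p under 0.05, and the exact Wilcoxon test called 1. Sdhd was 0.24, Sdhc 0.21, Ndufv2 0.17 and Ndufb8 0.15. The median was 0.04 and 0.15 within the sets. The other probe set of Ndufb8 gave -0.27. Sdhd and Ndufv2 passed without control 1 or reduced oxygen 5 and Sdhc without controls 1 or 2 (adjusted p from 0.0170).

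Blood cell lists in spleen passed only at the preset correlation. Neutrophil markers had 6 of 23 higher and 0 lower (8 and 0 adjusted over the list alone), with median 0.99 (adjusted p = 1.9e-06, but 0.765 with an estimated correlation). Beside Mmp8, gelatinase Mmp9 rose by 1.18, the granulocyte colony-stimulating factor receptor Csf3r by 1.12 and the integrin Itgam by 0.94. The median was 1.00 and 0.88 within the sets. Macrophage markers had 4 of 26 higher and 0 lower (6 and 0 adjusted over the list alone), with median 0.26 (adjusted p = 0.00485, but 0.765 with an estimated correlation). Cd14 rose by 1.15, Cd5l by 0.62, the scavenger receptor Msr1 by 0.47 and complement C1qc by 0.42. C1qc lost its call for 11 of 16 arrays left out (adjusted p to 0.0871). The median was 0.49 and -0.01 within the sets. Megakaryocyte markers had 1 of 18 higher and 0 lower (0 and 0 adjusted over the list alone), with median 0.34 (adjusted p = 0.000181, but 0.765 with an estimated correlation). Nrgn rose by 0.43, while Rgs18 was 0.40, Gp9 0.38 and Gng11 0.26. Rgs18 passed without reduced oxygen 1, 2 or 5, Gp9 without 1 or 2 and Gng11 without controls 6 or 8 (adjusted p from 0.0354). The median was 0.56 and 0.09 within the array sets.

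B cell markers had 0 of 23 higher and 5 lower in spleen (1 and 5 adjusted over the list alone), with median -0.29 (adjusted p = 0.0341, but 0.765 with an estimated correlation). The follicle-homing receptor Cxcr5 fell by 0.74, the transcription factors Spib and Pax5 by 0.69 and 0.52 and the low-affinity IgE receptor Fcer2a by 0.62. Fcer2a lost its call for 9 of 16 arrays left out (adjusted p to 0.0775) and Cxcr5 for 3, reduced oxygen 3 and controls 7 and 8 (adjusted p = 0.0517, 0.0564 and 0.0582). Reduced oxygen 4 stood apart, with a mean log2 intensity of B cell markers of 9.57, against 10.53 to 10.95 on the other 7 arrays of its group. Without it the spleen list: B cells had a median of -0.12 (adjusted p = 0.0992), and the call also ended without controls 1, 6, 7 or 8 or reduced oxygen 6 (adjusted p to 0.0670). Erythroid markers had 0 of 30 members called by limma over all genes or adjusted over the list alone, with median 0.52 (adjusted p = 0.00252, but adjusted p = 0.765 with an estimated correlation). Without adjustment 1 member was higher and 0 lower at p under 0.05, and the exact Wilcoxon test called 0. Ank1 was 0.88, Gfi1b 0.75, the erythropoietin receptor Epor 0.67 and Xk 0.22. Their median was -0.10 and 1.26 within the sets and 0.30 without control 7 (adjusted p = 0.0467). Cell cycle genes had 0 of 33 higher and 1 lower (0 and 1 adjusted over the list alone), with median 0.37 (adjusted p = 0.0106, but 0.765 with an estimated correlation). Ccnd1 fell by 0.60, while Ccnd3 was 0.39, Gins2 0.39 and Ccnd2 -0.33. Without control 2, Ank1, Gfi1b, Epor, Ccnd3 and Ccnd2 passed, and Ccnd3 also without control 3 (adjusted p from 0.0221). Their median was -0.18 and 0.82 within the sets. The list's call ended without controls 6, 7 or 8 or reduced oxygen 4 (adjusted p to 0.157), with median 0.21 without control 7. With the erythroid mean of each array as a covariate, the spleen list: cell cycle and proliferation had a median of -0.01 (adjusted p = 0.459). The spleen list: B cells (adjusted p = 0.291), the spleen list: NRF2 and oxidative stress targets (adjusted p = 0.201) and the spleen list: oxidative phosphorylation (adjusted p = 0.0796) then also missed the threshold.

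The other 22 lists did not pass in spleen. The p53 list had 5 higher and 5 lower of 19 (adjusted p = 0.15), immediate early genes 7 and 5 of 26 (adjusted p = 0.171), and interferon-stimulated genes 5 and 3 of 28 and apoptosis genes 5 and 3 of 24 (adjusted p = 0.179 each). PPAR-alpha targets had 3 and 0 of 19, angiogenesis 0 and 2 of 34 and cholesterol synthesis 0 and 4 of 26 (adjusted p = 0.183 each). Iron handling had 3 and 1 of 18 (adjusted p = 0.219), the circadian clock 6 and 4 of 17 (adjusted p = 0.222), metallothioneins 2 and 1 of 9 (adjusted p = 0.369), acute phase genes 1 and 3 of 17 (adjusted p = 0.418) and gluconeogenesis 1 and 1 of 13 (adjusted p = 0.659). T and NK cell markers had 3 and 1 of 27, the stress response list 3 and 1 of 29, heat shock proteins 1 and 1 of 18 and bone and stromal markers 2 and 0 of 16 (adjusted p = 0.929 each). No member was called by limma, over all genes or adjusted over the list alone, among bile acid and drug metabolism (0 of 9, adjusted p = 0.659), adipocytes (0 of 8, adjusted p = 0.70), ribosomal proteins (0 of 22, adjusted p = 0.789), skeletal muscle (0 of 12, adjusted p = 0.855), hepatocytes (0 of 8, adjusted p = 0.885) and pancreatic acinar markers (0 of 10, adjusted p = 0.929). At an unadjusted p under 0.05, 1 bile acid gene and 1 ribosomal protein were higher and 1 muscle gene was lower, and the exact Wilcoxon test called 0. Adjusted over the list alone, the counts that differed were 6 and 5 for p53, 7 and 3 for interferon, 0 and 2 for cholesterol synthesis, 3 and 2 for iron and for metallothioneins, 2 and 1 for T and NK cells and 1 and 0 for the stress response. Median, mean and test differed in sign for the clock, ribosomal proteins, skeletal muscle, the stress response, heat shock and acinar markers.

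**Figure D2:**
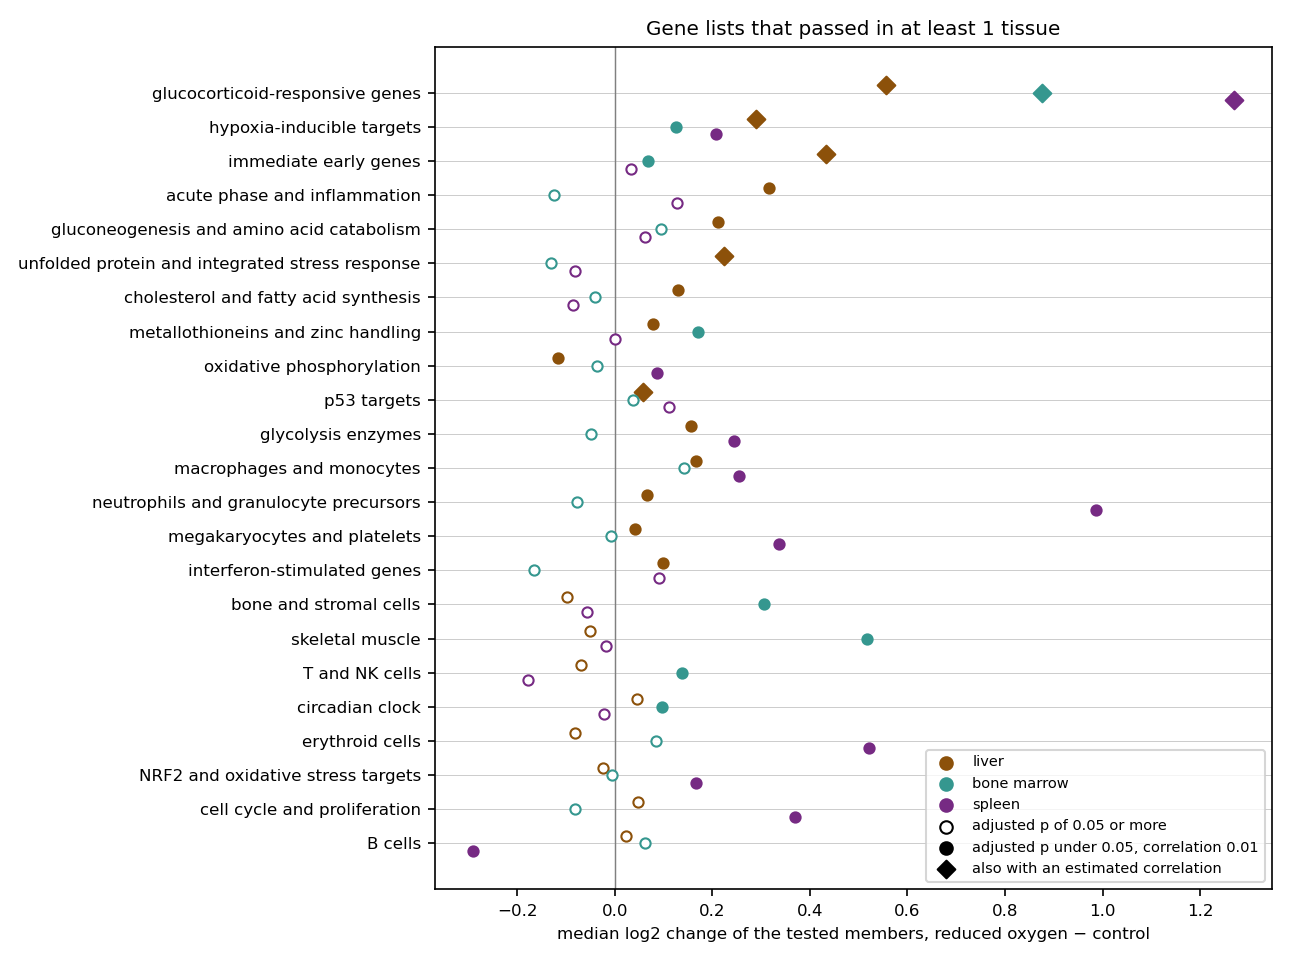
Median log2 change of the tested members of each list that passed in at least 1 tissue, in liver (brown), bone marrow (teal) and spleen (purple). Open points did not pass, filled circles passed at the preset correlation of 0.01, and diamonds passed also with an estimated correlation, as glucocorticoid-responsive genes did in every tissue.

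The response itself differed between liver and spleen for 1120 of 11378 genes, 538 more positive in liver and 582 more positive in spleen. In a simulation of this contrast, with noise drawn independently for each gene, 12.6% of calls were unchanged genes. Arrdc3 had the largest difference among the leading genes, falling by 2.88 in liver with 1.64 in spleen, a difference of -4.52 ± 0.26 (adjusted p = 4.29e-16). Tcim was 2.47 in liver and -0.65 in spleen, a difference of 3.12 ± 0.18, and the amino acid transporter Slc38a2 1.84 and -0.21, a difference of 2.05 ± 0.13. Snhg3 (3.66 and 0.60), Gadd45b (1.82 and -0.70) and Trp53inp1 (2.42 and 0.26) differed by 3.06 ± 0.22, 2.51 ± 0.19 and 2.16 ± 0.16. The adjusted p of these 6 was at most 1.73e-12. Ddit4 rose more in liver, by 2.73 (adjusted p = 7.22e-09), and Egln3 more in spleen, with -0.94 (adjusted p = 0.0180). Vegfa at 0.37, Hmox1 at 0.35 and Bnip3 at -0.05 did not pass (adjusted p = 0.124, 0.644 and 0.899).

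Liver and bone marrow differed for 314 of 11396 genes, 163 more positive in liver and 151 in bone marrow. Without bone marrow control 1, 170 were called as liver against bone marrow genes with a different response. Snhg3 was -0.02 in bone marrow, a difference of 3.69 ± 0.28, and Arrdc3 was 1.47 there, a difference of -4.35 ± 0.33. Slc38a2 (-0.32 in bone marrow) differed by 2.15 ± 0.17 and Cebpd, a C/EBP factor of the acute phase (2.26 in liver and -0.59 in bone marrow), by 2.85 ± 0.22. These 4 had adjusted p = 3.19e-12. Ccn1 was 0.17 in liver and 3.21 in bone marrow, a difference of -3.04 ± 0.26 (adjusted p = 9.07e-11), and Tcim differed by 2.45 ± 0.23 (adjusted p = 9.33e-10). Ddit4 at 0.91, Vegfa at 0.54 and Hmox1 at 1.03 did not pass (adjusted p = 0.218, 0.146 and 0.377).

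Spleen and bone marrow differed for 33 of 12124 genes, 11 more positive in spleen and 22 in bone marrow. The count was 12 without bone marrow control 1, 16 without control 2, 14 without reduced oxygen 3 and 16 without reduced oxygen 4, and 55 with no dim-gene filter, as spleen against bone marrow genes with a different response. Ccn1 was 0.30 in spleen, a difference of -2.91 ± 0.26 (adjusted p = 2.53e-09). Cebpd was 1.62 in spleen, a difference of 2.21 ± 0.22 (adjusted p = 1.83e-08), and Neto2 2.09 against -0.12, a difference of 2.21 ± 0.28. Ifit1bl2 (0.03 against -0.98), Egr2 (-0.84 against 0.63) and Pex11a (1.69 against 0.39) differed by 1.01 ± 0.14, -1.47 ± 0.22 and 1.30 ± 0.20. Ddit4 rose more in bone marrow, by -1.82 in spleen minus bone marrow (adjusted p = 0.0157). Egln3 at 0.55 (adjusted p = 0.764) and Vegfa at 0.17 (adjusted p = 0.891) did not pass.

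**Figure D3:**
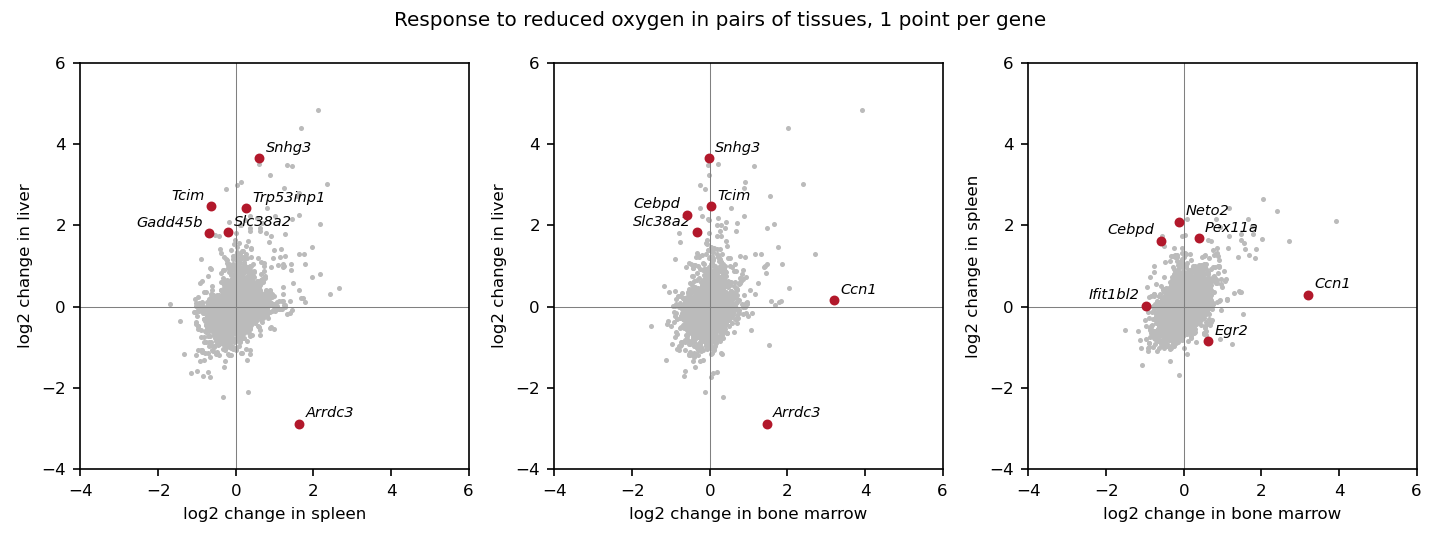
Log2 change of reduced oxygen minus control in pairs of tissues, with 1 point per gene tested in both and the 6 leading interaction genes of each pair labelled. Arrdc3 lies at -2.88 in liver and 1.64 in spleen, and Ccn1 at 3.21 in bone marrow and 0.30 in spleen.

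Many calls were shared between tissues. Of 11075 genes tested in all 3 tissues, 46 were higher and 135 lower in each, where independent lists would share 0.744 and 4.56. Genes higher in all 3 tissues included Ddit4, Mt1, Mt2, Dusp1, Fos, Per1, Errfi1, H3f3b, Ankrd37, Cdkn1a and Cirbp. Genes lower in all 3 tissues included Sox18, Zfp866, Zfp467 and Thap2. Spleen and bone marrow shared 145 higher calls, where independent lists would share 22.8, and 386 lower calls against 76.9, with 9 opposite calls. Liver and spleen shared 115 higher against 30.5 and 312 lower against 99.5, with 52 opposite. Liver and bone marrow shared 70 higher against 10.9 and 164 lower against 36.7, with 31 opposite. Fisher's exact p was at most 1.04e-37 for each of these 6 overlaps, and at most 1.39e-37 adjusted over 12 tests of overlap. In all, 830 genes were called the same way in more than 1 tissue. Tissues of the same mouse, if shared, would make these lists dependent.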

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

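The tests on the array sets, on Lcn2, on spleen neutrophil markers and on other splits of the arrays were set down after the data were seen; for the erythroid covariate the expected outcome was written before its result.

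The liver arrays of replicates 1 to 4 stood apart from those of 5 to 8 in both treatment groups. Their 30th percentiles of intensity ran from 17.8 to 18.7 and from 19.4 to 19.8, a gap of 0.664, as arrays made or normalized in separate sets would show. A split along these numbers called 5671 liver genes, against 1413 for the treatment, which points to a structure of the samples. Tissue taken at another time of day may contribute, since the mean absolute set effect of the circadian clock list, 0.314, lay at percentile 98.7 of random lists matched on mean expression, whose median was 0.225. Both explanations remain open. The clock gene Dbp varied in log2 intensity within a set, from 6.01 to 11.32 in liver controls 1 to 4. A difference in time of day between treatments, or in mice between sets, was not tested.

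Lcn2 differed widely between the reduced oxygen livers, at a log2 intensity of 7.15, 7.08, 13.81, 11.83, 7.07, 13.81, 13.00 and 13.33 for replicates 1 to 8, and stood at 8.50, 7.65, 11.98, 11.17, 9.24, 11.59, 10.09 and 10.96 in the spleens of these numbers. Neutrophils in the livers were not excluded: S100a8 was higher in reduced oxygen livers, and although Ltf, Camp and Ngp reached at most 5.51, 5.22 and 5.51, at least 8.52 below the level that bone marrow ratios to Lcn2 would give, those ratios need not hold in liver and rest on probe sets near the brightest value, 15.4. The array sets were argued against, because Lcn2 ranged over 6.73 and 6.74 within the sets, while the set means differed by 1.84. A state of the mouse that its organs share may contribute. Liver and spleen arrays of the same number and treatment deviated together, with a mean correlation across genes of 0.0879 over 16 number pairs, 12 of them positive, against -0.0017 for permuted numbers (one-sided permutation p = 0.0001, the smallest these permutations can give), though the labels do not say that numbers mark mice.

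Neutrophil markers were higher in spleen under reduced oxygen, with a median of 0.99, but the list did not pass with an estimated correlation (adjusted p = 0.765). S100a8 stood at 12.17, 11.37, 14.18, 13.88, 12.88, 14.24, 13.70 and 14.09 in reduced oxygen 1 to 8, against 11.72 to 13.38 in control. A lower share of B cells would raise T and NK cell markers alike, but their mean change was -1.04 relative to that of neutrophil markers, with a standard error of 0.459. The array sets were argued against by a median of at least 0.879 within each, and the erythroid share by a median of 0.773 with the erythroid mean as covariate. More neutrophils in the spleen, or a change in gene activity of resident ones, may account for it and cannot be separated with these values.

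A sample far from the others was found in 25 of 398 groups tested, and chance gives about 1 in 20. Each value is the log2 intensity of that sample. In liver controls these were Clec2d at 9.33 and Gadd45b at 7.14 in replicate 5 and Plek at 5.53 in replicate 2. Under reduced oxygen, liver replicate 3 stood apart for Foxq1 at 7.38, G6pc at 11.96, Id3 at 7.84, Hmox1 at 10.1, where the others ran from 7.40 to 8.08, and the p53 list mean at 8.56. Other reduced oxygen livers stood apart for Clec2d at 7.21 in replicate 8, Itgb3 at 6.27 in replicate 4, Snhg3 at 8.79 in replicate 6 and Tat at 13.6 in replicate 2. In bone marrow under reduced oxygen they were Eno3 at 7.92 in replicate 2 and Lum at 10.3 and Snai2 at 6.78 in replicate 4. Spleen control 6 stood apart for Adm at 6.93. Spleen reduced oxygen 4 stood apart for Adm at 7.53, Ankrd37 at 7.10, Cxcr5 at 7.93, Ddit4 at 11.4, Traf1 at 6.80 and the B cell list mean at 9.57. Further spleens under reduced oxygen were replicate 3 for Bnip3 at 9.39 and Tbx21 at 5.97 and replicate 6 for Ndufb8 at 10.97.

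Responses that differed between tissues by the interaction contrast, with adjusted p under 0.05, are given as differences of log2 changes. In liver minus spleen the stress and growth-arrest genes Btg2, Gadd45g, Gadd45b, Trp53inp1, Plk3, Cdkn1a and Jun differed by 3.14, 2.92, 2.51, 2.16, 1.89, 1.67 and 2.93. Tcim, Snhg3, Pfkfb3, Ddit4 and Noct differed by 3.12, 3.06, 2.96, 2.73 and 2.36, and Mt2 and Mt1 by 2.73 and 2.01. Slc38a2, Vcam1, Nfkbiz, Bhlhe40, Slc39a14 and Sgk1 differed by 2.05, 1.72, 1.53, 1.39, 1.24 and 1.22, and Ankrd37, Tat, Thap2 and Chac1 by 1.14, 1.13, 1.08 and 1.02. Smaller positive differences were those of Cebpg, Ttpal, Usp18, Insig2, Ccnd1, Atf3 and Dusp1 at 0.94, 0.91, 0.87, 0.84, 0.81, 0.65 and 0.65. Pax5, Cebpd, Sqle and Nfkbia followed at 0.65, 0.64, 0.56 and 0.46. The largest negative differences were those of Arrdc3, Osgin1, Errfi1, Il1r2, Phlda1, Pex11a and Pdk4 at -4.52, -2.44, -2.20, -2.12, -1.90, -1.47 and -1.37. Kcne4, Mmp9, Fzd7, Hhex, Csf3r, Egln3 and Zfp866 differed by -1.25, -1.19, -1.17, -1.07, -0.98, -0.94 and -0.86. Gsr, Irf1, Ndufv1, Sdhc and Cox5b differed by -0.68, -0.57, -0.39, -0.34 and -0.30, and Tpi1, Ndufv2 and Ndufb8 by -0.29, -0.28 and -0.28.

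In liver minus bone marrow Snhg3, Gadd45g, Pfkfb3, Noct, Btg2 and Cebpd differed by 3.69, 3.31, 3.26, 3.25, 3.01 and 2.85. Tcim, Mt1, Jun, Slc38a2, Gadd45b and Cdkn1a differed by 2.45, 2.31, 2.16, 2.15, 2.15 and 2.05, and Trp53inp1, Plk3, Usp18, Chac1, Bhlhe40 and Sgk1 by 1.88, 1.82, 1.60, 1.38, 1.37 and 1.34. Slc39a14, Snai2, Insig2, Cebpg, Thap2 and Ubxn7 differed by 1.22, 1.04, 0.82, 0.77, 0.71 and 0.67. Negative differences were those of Arrdc3, Ccn1, Phlda1, Egr1, Osgin1, Hhex and Id3 at -4.35, -3.04, -2.55, -2.46, -2.0015, -1.78 and -1.72. Klf9, Zbtb16, Errfi1, Pik3ip1 and Per1 differed by -1.68, -1.63, -1.60, -1.59 and -1.44, and Fzd7, Zfp866 and Irf1 by -1.12, -1.05 and -0.83. In spleen minus bone marrow Cebpd, Neto2, Pex11a, Kcne4 and Ifit1bl2 differed by 2.21, 2.21, 1.30, 1.02 and 1.01, and Ccn1, Egr3, Ddit4, Egr2 and Id3 by -2.91, -1.86, -1.82, -1.47 and -1.26. These fits used another probe set than the fit of 1 tissue for Vcam1 in liver (1.97, not 0.23), for Gsr, Mmp9 and Pik3ip1, and for Egr3 in liver against spleen.

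Chance could be excluded for the counts of genes called by treatment. Of 100 splits of the liver arrays 1, the real one, gave as many as 1413, and the highest other gave 692. Among 100 splits that part all 8 liver number pairs the highest other gave 573, and 96 of the others gave none. Of the 35 splits of the bone marrow arrays 1 gave as many as 979 and the highest other 0, and of 100 of the spleen arrays 1 gave as many as 2470 and the highest other 608. Chance could also be excluded for the differences between tissues, with 1120 against 805 at most for liver and spleen (1 of 100), 314 against 379 for liver and bone marrow (2 of 100) and 33 against 24 for spleen and bone marrow (1 of 100), and for the 830 genes called in more than 1 tissue, against 0 (1 of 100). Chance could not be excluded for the number of lists at the preset correlation, with 15 against 17 in liver (10 of 100 splits as large), 8 against 12 in bone marrow (16 of 35) and 11 against 17 in spleen (49 of 100). These splits ignored the numbers and array sets. Of 100 splits that part all 8 liver number pairs, 11 gave as many as 15 lists, and the highest other gave 18. With an estimated correlation few splits were as large, with 5 against 1 in liver (1 of 100) and against 4 among splits that part the pairs (1 of 100). It was 1 against 0 in bone marrow (1 of 35) and 1 against 1 in spleen, where another split tied (2 of 100).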

How the results depend on the processing

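The fits within the array sets, with the erythroid covariate and without the arrays holding muscle or pancreatic transcripts, and for the lists also the array set as a term, leaving out liver or spleen arrays, and the hypoxia and glucocorticoid lists without shared members, were chosen after the data were seen; the other alternatives were planned. For the 77 genes named in liver, 2272 of 2450 values under alternatives kept their direction and side of the threshold, 111 lost the call, 65 gained it and 2 turned. In bone marrow these were 829, 81, 18 and 7 of 935, and in spleen 2040, 82, 72 and 2 of 2196. Genes near background were not tested, which limits what can be said of dim genes, and 3 control arrays limit bone marrow. Where a count or direction changed below, the cause was not tested unless stated.

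The count of liver genes changed, 1413, was 2180 in 1 fit over all arrays, 2385 with the replicate block, 2666 with the array set as a term and 780 in replicates 1 to 4 alone, and ran from 1072 to 1570 with 1 array left out. The count of bone marrow genes changed, 979, was 1669 with array weights, 310 in 1 fit over all arrays and 0 with the exact Wilcoxon test, which cannot pass with 3 against 4 arrays, where limma called 979 and 3148 without adjustment. It ran from 408 to 909 with 1 array left out. The count of spleen genes changed, 2470, was 482 in replicates 1 to 4 alone, and ran from 2104 to 2874 with 1 array left out. The liver gene list shifts fell from 15 to 5 and the bone marrow gene list shifts from 8 to 1 with an estimated correlation, and the latter ran from 8 to 11 with 1 array left out. With 1 array left out the liver gene list shifts ran from 11 to 16 and the spleen gene list shifts from 9 to 11. The spleen gene list shifts, 11, were 1 with an estimated correlation, 4 with fry and 6 with the erythroid covariate, which ends the erythroid list's own call by construction. With array weights the liver against spleen genes with a different response were 1891, the liver against bone marrow genes with a different response 1461 and the spleen against bone marrow genes with a different response 902. Without a dim-gene filter the last count was 55. With 1 array left out these counts for liver against bone marrow ran from 170 to 302 and for spleen against bone marrow from 12 to 31. The genes called in more than 1 tissue were 139 when at least 1.5-fold change was required, fewer by construction.

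The liver Angptl4 log2 fold change turned to -0.0950 in replicates 5 to 8 alone and ran from -0.00572, without reduced oxygen 4, to 0.135 with 1 array left out. The bone marrow Hmox1 log2 fold change was -0.282 without control 1, -0.00106 without control 3, and -0.0717, -0.0997 and -0.253 without reduced oxygen 1, 2 and 3, with a highest value of 0.615. The bone marrow Mtf1 log2 fold change was 0.234 without control 1 and 0.0838 without control 3, with a lowest value of -0.456. The spleen Ndufb8 log2 fold change turned to -0.0601 over the mean of its probe sets, which differ in sign. The spleen Gins2 log2 fold change turned to -0.0228 in replicates 1 to 4 alone. The spleen list: cell cycle and proliferation turned to -0.0143 with the erythroid covariate. None of these genes was called in the fit of its tissue, and all but bone marrow Hmox1 passed in some alternative. Over the mean of probe sets liver Tnfaip3, Plek and Fzd7 were 0.55, 0.37 and -0.81, bone marrow Zbtb16 1.11 and spleen Pcdh18, Thap2 and Ttpal -1.18, -0.79 and -0.61, and without probe sets that may match several transcripts bone marrow Mt1 was 0.42 and spleen Zfp467 -0.67, all called.

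With the replicate block, which in bone marrow left out reduced oxygen 4, bone marrow genes changed numbered 932 and spleen genes changed 1962, and the lists that passed 15, 9 and 11 in liver, bone marrow and spleen. Same-number correlations ran from -0.0267 to 0.322 in bone marrow, with 2 of 3 arrays best with their own number, and from -0.478 to 0.313 in spleen, with 1 of 8. Among named genes the block ended the calls of Il2rb and Ncr1 in bone marrow and C1qc, Txnrd1 and Fcer2a in spleen, added Nr1d2 and Mtf1 in bone marrow and Vegfa in spleen, and changed no other call beside those given for liver. As a random block in the tissue differences, with consensus correlations of 0.145, 0.147 and 0.136, it gave 1522 liver against spleen genes with a different response, 464 liver against bone marrow genes with a different response and 45 spleen against bone marrow genes with a different response.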

Other observations

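The tests here, and the genes in the next paragraph, were chosen after the data were seen; for the hypoxia list members, Cirbp and Snhg genes the expected outcome was written before its result.

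Several genes moved within lists that did not pass as a whole. In liver the transferrin receptor Tfrc rose by 2.22 ± 0.14 (adjusted p = 3.54e-09), Rrm2, a subunit of ribonucleotide reductase, by 2.18 ± 0.20 (adjusted p = 2.91e-07) and the lipid droplet genes Plin4 and Plin5 by 2.10 ± 0.18 (adjusted p = 1.69e-07) and 1.46 ± 0.20 (adjusted p = 5.56e-05). In bone marrow the mitotic kinases Aurka, Plk1 and Cdk1 fell by 0.70 ± 0.08, 0.80 ± 0.11 and 0.39 ± 0.06 (adjusted p = 0.00278, 0.0052 and 0.0076). In spleen the haptoglobin gene Hp rose by 1.73 ± 0.33 (adjusted p = 0.00125) and the clock repressor Nfil3 by 1.08 ± 0.23 (adjusted p = 0.00311). Txnip, an inhibitor of thioredoxin and glucose uptake, rose in all 3 tissues, by 0.68, 0.85 and 0.67 in liver, bone marrow and spleen (adjusted p = 0.0204, 0.00758 and 0.000553).

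The hypoxia and glucocorticoid lists share Ddit4 and Angptl4. Without them the hypoxia list passed at the preset correlation in liver, bone marrow and spleen (adjusted p = 7.91e-16, 0.00368 and 3.59e-07). In liver this argued against them as the whole source of its shift. In bone marrow and spleen the full list failed with an estimated correlation, so this cannot decide there.

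Cirbp, a cold-inducible gene, rose in liver, bone marrow and spleen by 1.04, 1.86 and 1.42. A fall of body temperature may contribute, and the test on Rbm3, another cold-inducible gene, was void, because 0 tissues had a probe set that names Rbm3 alone.

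Zinc finger genes were among the largest falls in liver, bone marrow and spleen. The other members of the Zfp family had medians of -0.10, -0.05 and -0.12, with 8 higher and 35 lower of 228 in liver, 11 and 33 of 240 in bone marrow and 13 and 89 of 254 in spleen. Camera with an estimated correlation gave p = 0.123, 0.191 and 0.108, against p = 0.000893, 0.0386 and 1.65e-08 at the preset correlation, which leaves open whether the family fell beyond the genes named.

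Snhg3 rose in liver by 3.66. A rise of small nucleolar RNA host genes as a family was argued against. The 13 other Snhg genes tested, Gas5 included, had a median of -0.09 in liver (camera with an estimated correlation, p = 0.418), with Snhg5 higher by 0.36 and Snhg4, Snhg8 and Gas5 at -0.39, -0.31 and -0.42, all called.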
